A study of Mus musculus with 37 samples.

How the data were processed

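The series holds 37 arrays of total RNA from mammary glands of FVB mice, PTP1B wild type or knockout, either nulliparous in oestrus (P0) or at day 3, 7, 10 or 15 of pregnancy. Per the labels' protocols, RNA was amplified and labelled as sense-strand cDNA for an Affymetrix whole-transcript array. The deposited table gives 1 log2 intensity per probe set and array for 34760 probe sets, and values run from 2.10 to 13.71. Per the submitters' processing notes affy was used. The background correction, the summarisation and the normalisation between arrays are not given in the sources used here. The largest distance of an array's quantile from the mean of the arrays was 0.210. The number of arrays, 3 to 5 in a group, limits the precision, and nothing in the labels says whether replicates came from separate animals. No batch or date is given.

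Probe sets with exactly 1 gene symbol (21640) were used for genes, while 1321 with several symbols and 11799 with none named were left out, except in an alternative that tested all probe sets. Of 19937 genes 954 had over 1 probe set, of which the one with the highest mean was taken. Symbols of 19855 genes matched a RefSeq gene of the mouse assembly GRCm38.p6, which was used for names and gene order alone. A gene was tested where its value passed the 25th percentile of the table (4.96) in at least 3 arrays, which kept 16865 genes and left out 3072.

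All 37 arrays were fitted in limma 3.58.1 (R 4.3.3) with 1 mean per group, and contrasts were tested with its moderated statistic, two-sided, with Benjamini-Hochberg adjustment over the genes of a contrast and a threshold of 0.05. The contrasts were KO against WT at each stage, their unweighted mean over the 5 stages, an F test of whether the genotype difference varied between stages, and each pregnancy stage against P0 within a genotype. All contrasts against P0 of a genotype share the same P0 arrays. Tested on simulated data with the variance of each gene in these arrays, a log2 change of 1 was recovered in 86.6% to 98.5% of genes and a change of 0.5 in 52.2% to 76.1%, depending on the stage, with 3.24% to 8.33% of calls false. The simulated noise was normal and independent between genes and arrays. Correlated genes, outlying arrays and differences in cell content were not part of it, so these rates need not hold for the real arrays.

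There were 28 gene lists with 536 entries, of which 490 were measured. They covered milk proteins and secretory differentiation, fatty acid synthesis, prolactin and STAT5 signalling, progesterone receptor targets, oestrogen receptor targets, cell cycle, interferon-induced, immediate early and clock genes, insulin, IGF and leptin signalling, tyrosine phosphatases, receptor tyrosine kinases and chromosome 2 neighbours of Ptpn1. The others were markers of pan-epithelial, luminal progenitor, hormone-sensing luminal, myoepithelial, white adipocyte, brown adipocyte, B lymphocyte, T lymphocyte, plasma, macrophage, endothelial, fibroblast and matrix, skeletal muscle, Schwann and erythroid cells. A list score is the mean over its members of log2 values centred on each gene's mean over all arrays. Scores were compared within a stage by an exact permutation test and over stages by a permutation test within stages with 100000 resamples, both two-sided, with adjustment over the 28 lists. Members were counted after adjustment over all genes and adjusted over the list alone, and camera was run with a preset correlation of 0.01 and with an estimated correlation.

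The contrasts, lists, filter, alternatives and the rule for named genes were set before the data were examined, except where stated. The rule took Ptpn1, the 10 largest rises and 10 largest falls per contrast among called genes whose arrays do not overlap between groups (for the mean over stages, genes with 1 sign at all 5 stages), and up to 4 called members per list, leaving out predicted genes; where fewer than 5 passed, the 5 with the smallest p, and where no list member passed, up to 2, were given as values only. For the F test it took the 10 genes with the smallest p. Of these the text names examples, mostly ones that kept their call with each array left out in turn, a pick made after the values were seen. The alternatives were no filter, all probe sets, a further quantile normalisation, centring each array on its median, a trended and robust variance prior, array weights, the B and T lymphocyte score and the skeletal muscle score as covariates, a block for replicate numbers, a fit of the 2 compared groups alone, the median of a list, list members above the filter and each array left out in turn. Leaving out 7 arrays in doubt was added after seeing the data: a lymphocyte or muscle score over 1 above the median of the arrays, or Ptpn1 against the label.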

Results

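Total RNA of mammary glands was measured on 37 whole-transcript arrays of FVB mice that were wild type (WT) or knockout (KO) for PTP1B, the tyrosine phosphatase encoded by Ptpn1, which acts on the insulin receptor and on JAK2. The glands fell into 10 groups, both genotypes at P0 (nulliparous females in oestrus) and at days 3, 7, 10 and 15 of pregnancy (P3 to P15). The WT groups held 4, 3, 4, 3 and 4 arrays from P0 to P15, and the KO groups held 4, 3, 5, 3 and 4. Array medians lay between 6.52 and 6.79 on the log2 scale, and 16865 genes were tested. The series title names the effect of PTP1B deficiency on mammary gland development and differentiation. Genes are said to have risen, fallen or been called where their limma adjusted p was below 0.05, and changes are log2 differences ± SE. The 7 arrays in doubt were lymphocyte-rich (KO P10 replicates 2 and 3, WT P7 replicate 1), muscle-rich (WT P0 replicate 4, KO P3 replicate 1, KO P7 replicate 3) or the array labelled KO day 15 replicate 3.

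Ptpn1 (probe set 10478897) lay between 7.90 and 9.06 in the 18 WT arrays, with a mean of 8.66 ± 0.29 (SD, n = 18). In 18 of the 19 KO arrays it lay between 5.36 and 6.49, with a mean of 5.79 ± 0.30 (SD, n = 18). The array labelled KO day 15 replicate 3 read 8.68, inside the WT range. It was kept under its label, so every P15 comparison and the mean over stages draw on it. The fit shares 1 spread per gene over all groups, so this array also enters the SE and p values at the other stages. For Ptpn1 the SD was 1.60 in KO P15 beside 0.12 in KO P3 and 0.13 in WT P3, where the SE of the difference was 0.46. Ptpn1 was lower in KO glands by a log2 difference of -2.91 ± 0.40 at P0, -2.90 ± 0.46 at P3, -2.78 ± 0.38 at P7, -2.72 ± 0.46 at P10 and -2.23 ± 0.40 at P15. The limma adjusted p values were 0.000241, 0.00425, 0.000603, 0.000482 and 0.000440 in that order. The mean over stages was -2.71 ± 0.19, adjusted p = 8.52e-11, and the P15 difference was -3.03 without the array labelled KO day 15 replicate 3. The P3 call was lost without KO P3 replicate 3 (-2.93, adjusted p = 0.0839), and the P10 call with lymphocyte and muscle scores as covariates (-2.68, adjusted p = 0.551). Both fits held the array labelled KO day 15 replicate 3, which widens the spread of Ptpn1.

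**Figure D1:**
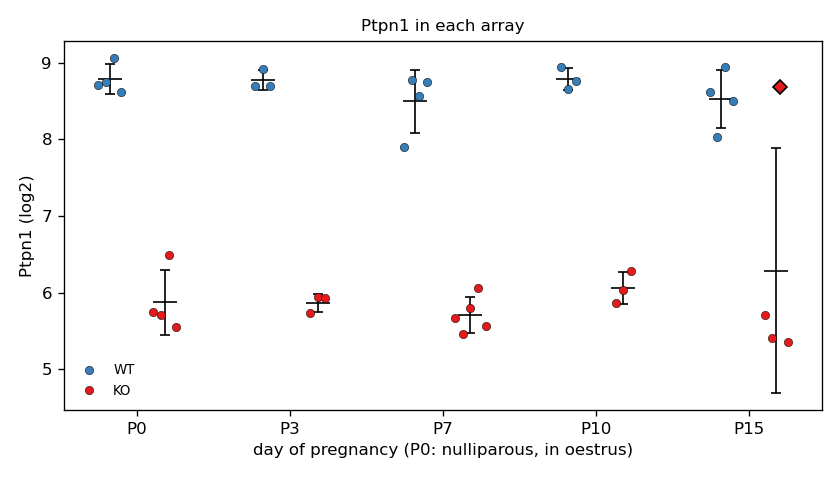
Ptpn1 (log2, vertical axis) in each array by day of pregnancy (horizontal axis) for WT and KO glands; points are arrays and bars give the group mean and SD. The diamond is the array labelled KO day 15 replicate 3, at 8.68, among WT arrays between 7.90 and 9.06.

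In the mean over the 5 stages, genes induced by interferon were higher in KO glands. Of the 17 list members 12 rose and 0 fell, and 16 passed adjusted over the list alone. Examples were Oas2, an antiviral oligoadenylate synthetase (0.81 ± 0.14, adjusted p = 0.00340), Irf7, a transcription factor of the interferon response (0.78 ± 0.15, adjusted p = 0.00552), and Usp18, which removes ISG15 from proteins (0.78 ± 0.16, adjusted p = 0.010). The list score was 0.55 higher in KO arrays (two-sided permutation p = 2e-05, adjusted over the 28 lists 0.00056). It was higher at 5 of 5 stages, by 0.53, 0.65, 0.34, 0.95 and 0.30 from P0 to P15, and 17 of the 19 KO arrays lay above the WT median of their stage. Single arrays moved these values, to 0.32 without KO P0 replicate 1, 0.38 without KO P3 replicate 3, 0.52 without WT P7 replicate 1, 0.51 without KO P10 replicate 2 and 0.19 without KO P15 replicate 2. Within single stages the two-sided exact permutation p was 0.114, 0.1, 0.119, 0.1 and 0.143, where 3 arrays against 3 cannot go below 0.1. The camera call of the list (adjusted p = 3.95e-21) was lost, with adjusted p = 0.0995 with an estimated correlation. Among P15 arrays the array labelled KO day 15 replicate 3 scored -0.53, within the WT range of -0.71 to -0.27, and the other KO arrays scored -0.18 to 0.12. Without the 7 arrays in doubt the score difference was 0.51 (permutation p = 3e-05) and the call of Usp18 was lost (0.71, adjusted p = 0.0532), as it was with lymphocyte and muscle scores as covariates (0.59, adjusted p = 0.0583).

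**Figure D2:**
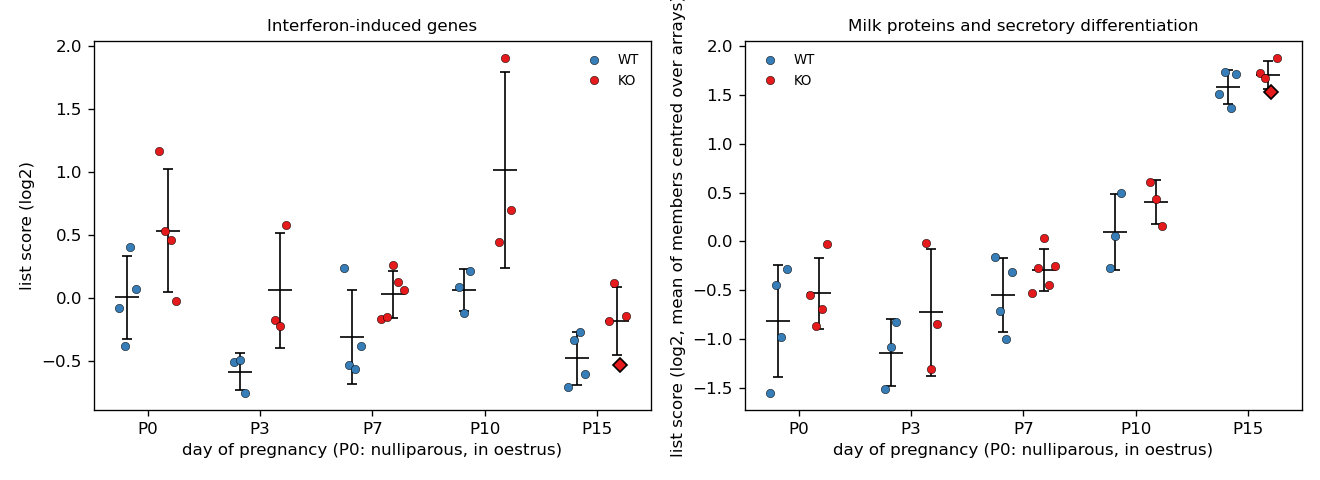
Scores of the interferon-induced and milk gene lists (log2, centred on the mean of all arrays, vertical axes) in each array by day of pregnancy for WT and KO glands; bars give the group mean and SD. The diamond is the array labelled KO day 15 replicate 3, whose interferon score was -0.53 beside WT scores of -0.71 to -0.27.

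Other genes that rose in the mean over stages were Gzmb, a granzyme (0.81 ± 0.12, adjusted p = 0.000702), Plac8 (0.86 ± 0.14, adjusted p = 0.00180), the chemokine Ccl5 (0.79 ± 0.16, adjusted p = 0.00887) and the lysozyme Lyz1 (0.75 ± 0.16, adjusted p = 0.00989), the last of which lost its call without the arrays in doubt (0.72, adjusted p = 0.0820) and with covariates (0.60, adjusted p = 0.0649). Plasma cell markers scored 0.23 higher (two-sided permutation p = 0.00517, adjusted 0.0483), at 5 of 5 stages. The permutation p adjusted over the 28 lists reached 0.0821 with 1 array left out, passing in 15 of 37 such fits, and was 0.101 with the replicate block. Of their 10 members 2 rose and 6 passed adjusted over the list alone, and the camera call (adjusted p = 0.00240) was lost, with adjusted p = 0.107 with an estimated correlation. The risen members were Jchain, the joining chain of secreted antibodies (0.89 ± 0.25, adjusted p = 0.0488), and Mzb1 (0.33 ± 0.09, adjusted p = 0.0498). Their calls were lost in 24 and 28 of the 37 fits with 1 array left out, where the adjusted p reached 0.0941 and 0.104. Without the arrays in doubt both calls were lost, with Jchain at 1.08 (adjusted p = 0.109) and Mzb1 at 0.22 (adjusted p = 0.266). With covariates they were lost at 0.86 (adjusted p = 0.145) and 0.19 (adjusted p = 0.224), and without the filter on dim genes the adjusted p was 0.0546 and 0.0553. Jchain was also lost after centring on the median (0.88, adjusted p = 0.0525) and Mzb1 with the replicate block (0.31, adjusted p = 0.0967).

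Fibroblast and matrix genes were lower in KO glands in the mean over stages. Of 20 members 8 fell and 0 rose, and 19 passed adjusted over the list alone. Examples were the collagens Col6a3 (-0.33 ± 0.06, adjusted p = 0.00415), Col6a2 (-0.33 ± 0.06, adjusted p = 0.00401) and Col5a2 (-0.28 ± 0.06, adjusted p = 0.0155). The list score differed by -0.25 (two-sided permutation p = 0.00289, adjusted 0.0405) and was higher in KO at P0 alone, where the difference was 0.26. Its permutation p adjusted over the 28 lists reached 0.0765 with 1 array left out, passing in 24 of 37 such fits, and was 0.101 with the replicate block and 0.0505 without the arrays in doubt. The camera call (adjusted p = 4.15e-17) was lost, with adjusted p = 0.0995 with an estimated correlation. Other genes that fell were Pdgfrb, a receptor of mesenchymal cells (-0.33 ± 0.05, adjusted p = 0.000613), the glucose transporter Slc2a10 (-0.47 ± 0.07, adjusted p = 0.000613) and the prostacyclin synthase Ptgis (-0.52 ± 0.09, adjusted p = 0.00246). The last 2 lie near Ptpn1 on chromosome 2, Slc2a10 22 tested genes and Ptgis 10 tested genes away. Pdgfrb was higher in KO at P0 (0.50) and lower at the later stages, from -0.14 at P7 to -0.71 at P3. Without the arrays in doubt Col6a2 (-0.31, adjusted p = 0.0538) and Col5a2 (-0.26, adjusted p = 0.109) lost their calls, and Col5a2 also with covariates (-0.25, adjusted p = 0.0564).

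Milk protein and secretory genes scored 0.28 higher in KO arrays (two-sided permutation p = 0.0277), which did not pass over the 28 lists (adjusted 0.155). The difference was 0.29, 0.42, 0.26, 0.31 and 0.12 from P0 to P15, with two-sided exact permutation p = 0.429, 0.5, 0.254, 0.3 and 0.371, and 15 of the 19 KO arrays lay above the WT median of their stage. At P0 it was 0.04, 0.12 and 0.46 without WT replicate 1, KO replicate 4 and WT replicate 4. At P3 it was 0.06, 0.23 and 0.71 without KO replicate 1, WT replicate 1 and KO replicate 2. At P7 it was 0.10 and 0.38 without WT replicates 3 and 1. At P10 it was 0.13, 0.21 and 0.51 without WT replicate 1, KO replicate 1 and WT replicate 3, and 0.17 after centring on the median. At P15 it was 0.05 and 0.06 without WT replicate 3 and KO replicate 4, 0.21 after centring, and 0.38 as the median over the list (two-sided exact permutation p = 0.0286, not adjusted over the lists). Of the 23 members 0 were called by limma in the mean over stages and 4 passed adjusted over the list alone, and the camera call (adjusted p = 2.80e-06) was lost, with adjusted p = 0.357 with an estimated correlation. The other lists did not pass the permutation test over stages after adjustment. Prolactin and STAT5 signalling differed by 0.09, progesterone receptor targets by -0.02, oestrogen receptor targets by -0.04, fatty acid synthesis by -0.04 and the insulin, IGF and leptin list by -0.02. Among epithelial lists the difference was 0.05 for pan-epithelial, 0.06 for luminal progenitor, -0.06 for hormone-sensing and -0.01 for myoepithelial markers. Cell cycle genes differed by -0.06, white adipocyte markers by -0.12, brown adipocyte markers by -0.15, endothelial markers by -0.11, Schwann cell markers by -0.14, erythroid markers by -0.15 and macrophage markers by 0.07. B and T lymphocyte markers differed by 0.37 and 0.41 and skeletal muscle markers by 0.18. The B difference was 0.61 without KO P10 replicate 1 and 0.24 without KO P10 replicate 2, and the T difference was 0.62 without KO P10 replicate 1. The muscle difference turned to -0.16 without KO P3 replicate 1 and was 0.42 without WT P0 replicate 4, 0.34 and 0.37 without KO P3 replicates 2 and 3, 0.09 and 0.10 without WT P0 replicates 1 and 2, and 0.08 without KO P7 replicate 3. The cell cycle difference turned to 0.07 without KO P3 replicate 3. With 1 array left out, 19 of the 28 list differences over stages moved by over 1.5 times or turned, and 5 turned, the others being fatty acid synthesis, progesterone receptor targets and myoepithelial markers. Immediate early genes differed by 0.04, clock genes by -0.06, tyrosine phosphatases by 0.01, receptor tyrosine kinases by -0.11 and the chromosome 2 neighbours of Ptpn1 by -0.03.

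In total 410 genes differed in the mean over stages, 220 higher and 190 lower in KO, and 3007 had an unadjusted p below 0.05. The fit without the arrays in doubt called 59, 57 of them shared. Leaving out KO P10 replicate 1 gave 1831, WT P0 replicate 2 gave 700, KO P10 replicate 2 gave 156, WT P3 replicate 2 gave 194 and KO P10 replicate 3 gave 218. Counts of 238, 257, 262, 243, 247, 266 and 268 came without WT P0 replicate 1, KO P0 replicate 3, WT P7 replicate 2, WT P7 replicate 3, KO P7 replicate 3, WT P10 replicate 1 and WT P15 replicate 4.

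At P0, before pregnancy, KO glands had higher Egr2, a zinc finger transcription factor (1.58 ± 0.27, adjusted p = 0.00211), Olfm4 (1.45 ± 0.21, adjusted p = 0.000301), the hyaluronan synthase Has2 (1.39 ± 0.22, adjusted p = 0.00122) and the matrix protein gene Frem1 (1.31 ± 0.20, adjusted p = 0.000825), with n = 4 arrays in each genotype. Them5 (1.85 ± 0.36, adjusted p = 0.00834) and Sprr2f (1.43 ± 0.20, adjusted p = 0.000241) also rose. Slpi, a secreted protease inhibitor, fell (-1.99 ± 0.36, adjusted p = 0.00425). Among lists, 1 member of 15 rose for prolactin and STAT5 signalling, namely Socs2, a feedback inhibitor of cytokine receptors (0.92 ± 0.15, adjusted p = 0.00122). Of 15 progesterone receptor targets 2 rose, Id4 (1.04 ± 0.24, adjusted p = 0.0208) and Adamts18 (0.87 ± 0.18, adjusted p = 0.00992), and 3 passed adjusted over the list alone. Sdc1 (0.88 ± 0.17, adjusted p = 0.00834) was the 1 of 10 plasma cell markers that rose, and Pdgfrb (0.50 ± 0.10, adjusted p = 0.00838) was 1 of 2 risen receptor tyrosine kinases of 17. Cell cycle genes had a mean difference of 0.81 with 0 of 33 called by limma and 15 passing adjusted over the list alone. Pan-epithelial markers had a mean of 0.50 with 0 of 19 called and 13 adjusted over the list alone, and macrophage markers a mean of 0.63 with 0 of 17 called and 11 adjusted over the list alone. The cell cycle difference was 0.46 without KO P0 replicate 4, whose score was 0.90. Without WT P0 replicate 2 the macrophage difference was 0.38 and the pan-epithelial difference 0.76. The pan-epithelial scores of WT P0 replicates 1 to 4 were -0.96, 0.30, -0.67 and -0.55, and those of KO P0 replicates 1 to 4 were -0.44, 0.27, 0.09 and 0.22. The gene differences at P0 were not separated from this difference in epithelial markers. Camera called these 3 lists (adjusted p = 8.97e-11, 2.22e-08 and 3.81e-08), each lost with adjusted p = 0.401 with an estimated correlation.

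Skeletal muscle markers had a mean difference of -1.57 at P0 (two-sided exact permutation p = 0.0286, n = 4 against 4), which did not pass over the 28 lists (adjusted 0.424), with WT P0 replicate 4 at a score of 4.77, and -0.39 without it. In total 286 genes differed, 215 higher and 71 lower, with 3504 at an unadjusted p below 0.05. Centring each array on its median gave 404 higher and 35 lower. Without the arrays in doubt 104 genes were called, 79 of them shared, and with the P0 arrays alone 2, where the 12 genes named above for P0 had an adjusted p of 0.209 to 0.317. The count was 81 without WT replicate 1, 1811 without WT replicate 2, 69 without WT replicate 4, 91 without KO replicate 2 and 94 without KO replicate 3. Id4 lost its call without WT replicate 1 (0.82, adjusted p = 0.0999), WT replicate 4 (1.04, 0.0638), KO replicate 2 (0.92, 0.0782) or KO replicate 4 (0.89, 0.0629) and without the arrays in doubt (1.04, 0.0567), and Adamts18 without WT replicate 1 (0.77, 0.0539) or KO replicate 2 (0.71, 0.0553).

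At P3 the genes that fell in KO glands included Slpi (-2.11 ± 0.42, adjusted p = 0.0255), Frem1 (-1.36 ± 0.24, adjusted p = 0.00782), Ptgis (-1.34 ± 0.22, adjusted p = 0.00425), the homeobox gene Alx4 (-0.80 ± 0.13, adjusted p = 0.00425) and Pdgfrb (-0.71 ± 0.12, adjusted p = 0.00425), with n = 3 arrays in each genotype. Tph1, a tryptophan hydroxylase, was the 1 gene that rose (1.24 ± 0.24, adjusted p = 0.0226). Matrix genes had a mean difference of -0.48 (-0.31 without KO P3 replicate 1), with 0 of 20 called by limma and 15 passing adjusted over the list alone, and a camera call (adjusted p = 1.06e-18) lost with adjusted p = 0.134 with an estimated correlation. Cell cycle genes had a mean of -0.72 with 0 of 33 called, and camera adjusted p = 6.75e-12 became adjusted p = 0.646 with an estimated correlation. That mean rested on KO P3 replicate 3, at a score of -1.42, and was -0.04 without it, -1.21 without KO P3 replicate 1 and -0.48 without WT P3 replicate 3. Skeletal muscle markers had a mean of 1.90, with KO P3 replicate 1 at a score of 5.05, and 0.17 without it. In total 20 genes differed, 1 higher and 19 lower, with 1198 at an unadjusted p below 0.05.

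All 6 named P3 genes lost their calls without KO replicate 3, with Slpi at -2.21 (adjusted p = 0.123), Frem1 at -1.07 (0.168), Ptgis at -1.29 (0.0923), Alx4 at -0.68 (0.0923), Pdgfrb at -0.62 (0.0923) and Tph1 at 1.07 (0.301). They also lost them without WT replicate 3, with Slpi at -1.96 (adjusted p = 0.290), Frem1 at -1.22 (0.137), Ptgis at -1.21 (0.0921), Alx4 at -0.74 (0.0619), Pdgfrb at -0.64 (0.0921) and Tph1 at 1.19 (0.187). Without KO replicate 1 the adjusted p was 0.113 for Slpi, 0.0656 for Frem1, 0.0696 for Ptgis and 0.0785 for Tph1. Without WT replicate 2 it was 0.0580 for Frem1 and 0.224 for Tph1, and without WT replicate 1 it was 0.0715 for Slpi. The count was 9, 2, 3, 114 and 0 without WT replicate 2, WT replicate 3, KO replicate 1, KO replicate 2 and KO replicate 3, and 2 without the arrays in doubt. There Slpi (-2.04, adjusted p = 0.0994), Frem1 (-1.34, 0.0810), Ptgis (-1.16, 0.0810), Tph1 (1.27, 0.0810) and Pdgfrb (-0.75, 0.0577) lost their calls. With the replicate block Frem1 (adjusted p = 0.0938), Alx4 (0.0556) and Pdgfrb (0.0556) lost theirs, as did Slpi with covariates (-1.87, 0.139) and Frem1 with array weights (-0.99, 0.107). With the P3 arrays alone all 6 lost their calls, at an adjusted p of 0.488 to 0.987.

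At P7 Ptpn1 was the 1 gene that limma called among 16865, and 443 had an unadjusted p below 0.05 (n = 4 WT and 5 KO arrays). Slpi had a difference of -1.49 ± 0.34 and was not called, but passed with the replicate block (-1.53, limma adjusted p = 0.00493), with array weights (0.0219) and with the P7 arrays alone (0.00439). Of the 17 interferon-induced genes 0 were called, with a mean of 0.34 (0.52 without WT P7 replicate 1) and a camera adjusted p of 2.21e-07, lost with adjusted p = 0.793 with an estimated correlation. Brown adipocyte markers had a mean of -1.10 over the tested members (-1.03 over all 13) with 0 of 12 called and 1 adjusted over the list alone, and camera adjusted p = 3.29e-08 became adjusted p = 0.793 with an estimated correlation.

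At P10 lymphocyte genes were far higher in KO glands (n = 3 arrays in each genotype). All 16 T lymphocyte markers and 15 of 16 B lymphocyte markers rose, and 16 of each passed adjusted over the list alone. Examples were the B cell receptor gene Cd79a (4.08 ± 0.70, adjusted p = 0.000491), the B cell antigen Ms4a1 (3.87 ± 0.89, adjusted p = 0.00319), Cd3e of the T cell receptor complex (2.95 ± 0.49, adjusted p = 0.000419), Cd8b1 (2.87 ± 0.52, adjusted p = 0.000571), Il7r (3.40 ± 0.70, adjusted p = 0.00131) and the homing receptor Ccr7 (3.06 ± 0.60, adjusted p = 0.000951). The rise rested on KO replicates 2 and 3, whose lymphocyte scores were 3.33 and 3.30, while KO replicate 1 scored -0.07. Without the arrays in doubt, which leaves KO replicate 1 alone with a spread taken from the other groups, Cd79a was 0.88, Il7r 0.43, Cd3e 0.97, Cd8b1 0.60, Ccr7 0.25 and Ms4a1 -0.19, and 0 of these were called. Ms4a1 was 5.90 without KO replicate 1, 2.79 (adjusted p = 0.0687) without KO replicate 2 and 2.92 (adjusted p = 0.0540) without KO replicate 3. Camera called both lists (adjusted p = 6.91e-14 for B and 4.86e-18 for T), lost with adjusted p = 0.225 and 0.225 with an estimated correlation.

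**Figure D3:**
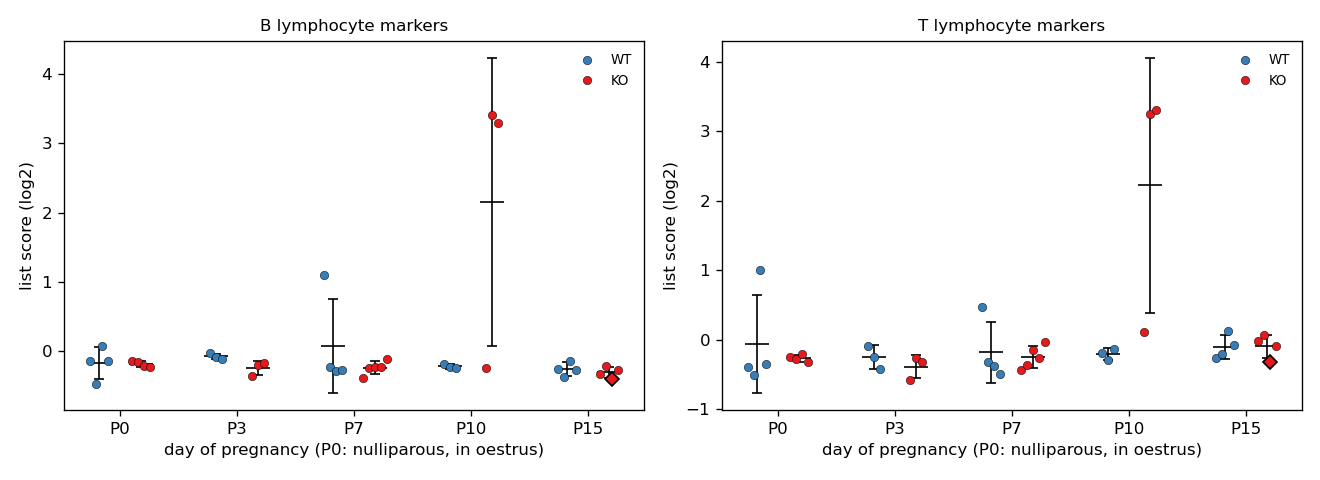
Scores of B and T lymphocyte markers (log2, centred on the mean of all arrays, vertical axes) in each array by day of pregnancy for WT and KO glands; bars give the group mean and SD. At P10 a pair of the 3 KO arrays lies far above the rest, with mean lymphocyte scores of 3.33 and 3.30, and the remaining one scores -0.07.

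At P10 8 of 17 interferon-induced genes rose (10 adjusted over the list alone), among them the antiviral GTPase Mx1 (1.95 ± 0.43, adjusted p = 0.00229; 0.95 without KO replicate 2). The interferon scores of KO replicates 1, 2 and 3 were 0.44, 1.90 and 0.70, and WT arrays scored -0.12 to 0.22. Of 10 plasma cell markers 3 rose and 1 fell (7 adjusted over the list alone), with Mzb1 at 1.56 ± 0.22. Tyrosine phosphatases went both ways, 3 of 20 higher and 8 lower (14 adjusted over the list alone), and their median was -0.27 where their mean was 0.04 and camera pointed down. The higher ones included Ptpn22 (2.03 ± 0.33), Ptpn6 (1.72 ± 0.29) and Ptprc (1.99 ± 0.38), all expressed in blood cells. Of the 15 endothelial markers 9 fell (11 adjusted over the list alone), with Cdh5 at -0.70 ± 0.14. Of the 20 matrix genes 10 fell (11 adjusted over the list alone), with Col6a3 at -0.73 ± 0.15 and Col15a1 at -0.99 ± 0.20. Among 10 hormone-sensing luminal markers 5 fell (5 adjusted over the list alone), with Esr1, the oestrogen receptor, at -0.86 ± 0.18 and Ptn at -0.77 ± 0.18. Receptor tyrosine kinases fell in 7 of 17 (8 adjusted over the list alone), with Erbb2 at -0.71 ± 0.15 and Pdgfrb at -0.62 ± 0.12. Camera adjusted p was 3.15e-07 for interferon, 2.89e-06 for endothelial, 2.68e-05 for matrix and 0.000192 for kinase genes, lost with adjusted p = 0.370, 0.324, 0.430 and 0.263 with an estimated correlation.

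In total 2905 genes differed at P10, 1366 higher and 1539 lower, with 5199 at an unadjusted p below 0.05. Without the arrays in doubt KO replicate 1 was left alone and assumed to vary like the arrays of other groups, Ptpn1 was the 1 gene called, and 0 of the other genes named at P10 kept their calls. The mean difference then was -0.33 instead of -0.42 for matrix genes, -0.33 instead of -0.52 for hormone-sensing markers, -0.25 instead of -0.41 for receptor tyrosine kinases, -0.17 instead of -0.54 for endothelial markers and 0.38 instead of 0.95 for interferon-induced genes. With lymphocyte and muscle scores as covariates limma called 0 genes, and with the P10 arrays alone 1, where the other genes named at P10 had an adjusted p of 0.184 to 0.223. Centring each array on its median moved the median of all genes by -0.17 and gave 941 higher and 3954 lower, while a further quantile normalisation gave 1274 and 2223. Leaving out WT replicate 1, KO replicate 1, KO replicate 2 or KO replicate 3 gave 1729, 4872, 841 or 1147 genes.

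At P15, where the array labelled KO day 15 replicate 3 counts as KO, the serum amyloid gene Saa2 (3.10 ± 0.48, adjusted p = 0.000100), the respiratory chain genes Cox8b (2.17 ± 0.43, adjusted p = 0.00126), also a brown adipocyte marker, and Uqcr11 (1.37 ± 0.18, adjusted p = 2.02e-05), the stress response gene Nupr1 (1.09 ± 0.14, adjusted p = 1.99e-05) and Cd1d1 (1.10 ± 0.22, adjusted p = 0.00143) rose, with n = 4 arrays in each genotype. Matrix genes fell in 11 of 20 (17 adjusted over the list alone), and their score differed by -0.52 (two-sided exact permutation p = 0.0286), which did not pass over the 28 lists (adjusted 0.2). Oestrogen receptor targets (-0.11) and Schwann cell markers (-0.21) had the same exact p and adjusted value. Examples were Fn1, which encodes fibronectin (-1.10 ± 0.20, adjusted p = 0.000514), and, beyond the list, Hmcn1 (-1.65 ± 0.27, adjusted p = 0.000190), the secreted Wnt antagonist Sfrp4 (-2.07 ± 0.51, adjusted p = 0.00738) and Igfbp6 (-1.49 ± 0.28, adjusted p = 0.000648). Camera called the matrix list (adjusted p = 7.04e-13), lost with adjusted p = 0.472 with an estimated correlation. Receptor tyrosine kinases fell in 4 of 17 (5 adjusted over the list alone), with Pdgfra at -0.83 ± 0.16 and Pdgfrb at -0.66 ± 0.10. White adipocyte markers rose in 4 of 19 (5 adjusted over the list alone), with Retn, which encodes resistin, at 0.42 ± 0.09 and Fabp4 at 0.33 ± 0.08. Brown adipocyte markers scored 0.82 higher (two-sided exact permutation p = 0.0286, adjusted over the 28 lists 0.2, not passing), with 1 of 12 risen (1 adjusted over the list alone), and camera did not call them (adjusted p = 0.110, and 0.978 with an estimated correlation). Of 23 milk genes 1 rose (1 adjusted over the list alone), the casein gene Csn1s2b (1.37 ± 0.33, adjusted p = 0.00572). Of 21 immediate early genes 4 rose and 1 fell (5 adjusted over the list alone), with Jun at 0.77 ± 0.13, and of 26 insulin, IGF and leptin genes 2 fell, with the adaptor Grb10 at -0.61 ± 0.14.

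In total 1873 genes differed at P15, 1143 higher and 730 lower, with 4013 at an unadjusted p below 0.05. Centring each array on its median gave 2311 higher and 337 lower. Without the array labelled KO day 15 replicate 3 and the other arrays in doubt 2014 genes were called, 1550 of them shared, and the 16 genes named here kept their calls.

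The genotype difference itself varied between stages in 3042 genes by the limma F test, with 5821 at an unadjusted p below 0.05. Ccnt1, a cyclin of transcription elongation, was 0.64 higher in KO at P10 and -0.71 at P15 (F adjusted p = 1.46e-06). Alx4 went from 0.75 at P0 to -0.80 at P3, Pdgfrb from 0.50 to -0.71 and Frem1 from 1.31 to -1.36 (F adjusted p = 8.37e-06, 1.62e-05 and 1.79e-05). Uqcr11 was -0.96 at P10 and 1.37 at P15 (F adjusted p = 9.18e-05). By list, 15 of 16 B lymphocyte, 15 of 16 T lymphocyte, 14 of 20 matrix and 9 of 20 phosphatase genes varied, against 0 of 33 cell cycle, 0 of 23 milk and 0 of 17 interferon-induced genes. Adjusted over the list alone the counts were 15, 16, 17, 14, 0, 0 and 0. With the arrays in doubt left out 492 genes varied, 462 of them shared, and the count was 4939, 1540 or 1632 without KO P10 replicate 1, 2 or 3.

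In WT glands, pregnancy day 3 brought higher cell cycle genes than P0 (n = 3 and 4 arrays). Of the 33 list members 32 rose and 33 passed adjusted over the list alone, among them the spindle checkpoint kinase Bub1 (2.71 ± 0.50, adjusted p = 0.000505), the cyclin Ccna2 (2.34 ± 0.52, adjusted p = 0.00246), the kinesin Kif11 (2.27 ± 0.51, adjusted p = 0.00258) and Top2a (2.15 ± 0.45, adjusted p = 0.00156). Endothelial markers fell in 12 of 15 (14 adjusted over the list alone), with Vwf at -1.08 ± 0.19 and Pecam1 at -0.95 ± 0.16. Camera called both lists (adjusted p = 1.50e-20 and 1.19e-10), lost with adjusted p = 0.454 and 0.454 with an estimated correlation. Ido1, which degrades tryptophan (-4.56 ± 0.53, adjusted p = 2.94e-06), Clca1 (-2.97 ± 0.41, adjusted p = 2.53e-05), Tph1 (-2.58 ± 0.22, adjusted p = 1.49e-08) and Btn1a1, a milk fat globule gene (-2.17 ± 0.35, adjusted p = 0.000164), fell. Serpinb11 (3.56 ± 0.63), the defensin Defb1 (3.01 ± 0.42) and Egr2 (2.47 ± 0.29) rose, as did 5 of 15 progesterone receptor targets (7 adjusted over the list alone), with Adamts18 at 1.38 ± 0.19 and Tnfsf11, which encodes RANKL, at 0.83 ± 0.17. In total 3050 genes differed, 1954 higher and 1096 lower, and 1072 without WT P3 replicate 3. With these 2 groups alone Clca1 (adjusted p = 0.0750), Ccna2 (0.0526) and Pecam1 (0.0577) lost their calls. Centring on the median moved the median of all genes by -0.11 and gave 1429 higher and 2123 lower, and quantile normalisation gave 1576 and 1745.

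At P7 WT glands differed from P0 in 4940 genes, 2617 higher and 2323 lower (n = 4 and 4). Cell cycle genes rose in 27 of 33 (30 adjusted over the list alone), with Bub1 at 2.34 ± 0.46, Kif11 at 2.19 ± 0.47 and Mki67 at 2.01 ± 0.41. Myoepithelial markers rose in 11 of 17 (13 adjusted over the list alone), luminal progenitor markers in 8 of 15 (8 adjusted over the list alone) and pan-epithelial markers in 11 of 19 (11 adjusted over the list alone). Examples were the secreted Wnt agonist Rspo1 (3.59 ± 0.48, adjusted p = 4.76e-06), the alveolar transcription factor Elf5 (1.20 ± 0.33, adjusted p = 0.00676) and the epithelial factor Ehf (1.87 ± 0.29, adjusted p = 3.69e-05). Camera called cell cycle (adjusted p = 2.12e-12), myoepithelial (5.57e-06), luminal progenitor (0.00169) and pan-epithelial genes (0.00138), lost with adjusted p = 0.565, 0.565, 0.565 and 0.791 with an estimated correlation. Tnfsf11 (1.48 ± 0.16), Adamts18 (1.92 ± 0.18), the receptor gene Erbb4 (1.97 ± 0.27), the connexin Gjb2 (2.88 ± 0.52) and Olah, the thioesterase of medium-chain fatty acid synthesis (2.20 ± 0.53), rose. Foxa1 (-1.30 ± 0.20), Ido1 (-4.55 ± 0.49) and Clca1 (-3.03 ± 0.38) fell. After centring on the median there were 2250 higher and 3044 lower, and 2989 genes were called without the arrays in doubt, 2747 of them shared. With these 2 groups alone Elf5 lost its call (adjusted p = 0.0785).

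At P10 a minority of milk genes had risen in WT glands (n = 3 and 4). Of 23 members 9 rose and 1 fell (12 adjusted over the list alone), with Glycam1 at 4.66 ± 1.12, Olah at 3.87 ± 0.57 and the whey protein gene Wap at 2.78 ± 0.70. The Wap call was lost without WT P10 replicate 3 (2.19, adjusted p = 0.0545). Prolactin and STAT5 genes rose in 7 of 15 (8 adjusted over the list alone), with Elf5 at 1.55 ± 0.35, Erbb4 at 1.48 ± 0.29 and Igf2 at 1.37 ± 0.23. Hormone-sensing luminal markers fell in 6 of 10 and rose in 1 (7 adjusted over the list alone), with Foxa1 at -1.90 ± 0.22, Ptn at -1.77 ± 0.17 and the progesterone receptor Pgr at -1.14 ± 0.31. Cell cycle genes rose in 26 of 33 (31 adjusted over the list alone), with Bub1 at 2.08 ± 0.50. The polymeric immunoglobulin receptor Pigr (2.90 ± 0.35), Gjb2 (3.56 ± 0.56) and Rspo1 (3.53 ± 0.52) rose, and Ido1 (-4.54 ± 0.53) and Clca1 (-3.30 ± 0.41) fell. Camera called the milk, prolactin, hormone-sensing and cell cycle lists (adjusted p = 0.00995, 0.000597, 9.19e-05 and 4.97e-12), lost with adjusted p = 0.808, 0.525, 0.265 and 0.709 with an estimated correlation. In total 3603 genes differed, 1965 higher and 1638 lower, and 1610 without WT P10 replicate 2. Clca1 (adjusted p = 0.0575), Glycam1 (0.0513), Wap (0.0553), Elf5 (0.109), Pgr (0.170) and Bub1 (0.0567) lost their calls with these 2 groups alone.

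At P15 most milk genes had risen in WT glands (n = 4 and 4). Of 23 members 21 rose and 1 fell (22 adjusted over the list alone), with Olah at 6.11 ± 0.53, Wap at 5.82 ± 0.65, Glycam1 at 5.41 ± 1.04 and the lipase Cel at 4.45 ± 0.56. Gjb6 (5.16 ± 0.44), Gjb2 (5.03 ± 0.52), Atp13a4 (4.96 ± 0.24), Pigr (4.60 ± 0.33) and Gldc, the glycine decarboxylase (4.11 ± 0.18), rose with them. Prolactin and STAT5 genes rose in 9 of 15 and fell in 1 (10 adjusted over the list alone), with Elf5 at 2.97 ± 0.33 and Erbb4 at 2.73 ± 0.27. Progesterone receptor targets rose in 10 of 15 and fell in 3 (13 adjusted over the list alone), with Tnfrsf11a, which encodes RANK, at 2.04 ± 0.17, Stc1 at 2.04 ± 0.15 and Lgr4 at 1.97 ± 0.16. Hormone-sensing luminal markers fell in 9 of 10 and rose in 1 (10 adjusted over the list alone), with Foxa1 at -3.04 ± 0.20, Ptn at -2.96 ± 0.15, Esr1 at -1.29 ± 0.16 and Pgr at -1.28 ± 0.29. White adipocyte markers fell in 17 of 19 (17 adjusted over the list alone), with Pck1 at -3.19 ± 0.50 and Plin4 at -1.56 ± 0.22, and brown adipocyte markers in 10 of 12 with 1 higher (11 adjusted over the list alone), with Ucp1 at -3.96 ± 1.18 and Cox8b at -3.75 ± 0.43. Cell cycle genes rose in 21 of 33 (21 adjusted over the list alone), with Hells at 2.04 ± 0.47 and Mki67 at 1.60 ± 0.41. Ido1 (-4.61 ± 0.49) and Clca1 (-3.51 ± 0.38) fell. Camera adjusted p was 2.60e-11 for milk, 9.27e-06 for hormone-sensing and 1.51e-08 for white adipocyte genes, lost with adjusted p = 0.211, 0.148 and 0.435 with an estimated correlation. In total 8238 genes differed, 3641 higher and 4597 lower. Centring on the median moved the median of all genes by -0.25 and gave 2230 higher and 8433 lower, and quantile normalisation moved it by -0.20 and gave 3097 and 7527.

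In KO glands at P3 cell cycle genes did not pass against P0, with 0 of 33 called by limma, 0 adjusted over the list alone and a mean of 0.11 (n = 3 and 4). The mean was 0.79 without KO P3 replicate 3, whose score was -1.42, and 0.47 without KO P0 replicate 4. It was -0.38, -0.07, -0.07 and -0.05 without KO P3 replicate 1, KO P3 replicate 2, KO P0 replicate 1 and KO P0 replicate 2. The F test, which covers the difference between genotypes, also called 0 of them, so the WT and KO responses were not shown to differ. Matrix genes fell in 15 of 20 (19 adjusted over the list alone), with Col6a1 at -0.998 ± 0.13 and Thbs2 at -1.58 ± 0.27. Macrophage markers fell in 12 of 17 (13 adjusted over the list alone), with Itgam at -1.49 ± 0.25. Fatty acid synthesis genes rose in 6 of 19 (8 adjusted over the list alone), with Acly at 1.27 ± 0.28 and Elovl6 at 1.17 ± 0.28. Pan-epithelial markers fell in 4 of 19 (4 adjusted over the list alone), with Krt18 at -0.76 ± 0.19 and Krt19 at -0.87 ± 0.23. Camera called matrix, macrophage and fatty acid synthesis genes (adjusted p = 1.38e-12, 4.27e-08 and 0.000113), lost with adjusted p = 0.213, 0.340 and 0.600 with an estimated correlation. Ido1 (-5.54 ± 0.53), Pate6 (-4.36 ± 0.51), Clca1 (-4.09 ± 0.41), Muc13 (-3.23 ± 0.36), Sprr1a (-2.74 ± 0.30) and Pgr (-1.38 ± 0.31) fell, and Tnfsf11 (0.87 ± 0.17) and Defb1 (2.06 ± 0.42) rose. Skeletal muscle markers had a mean of 1.93 (0.21 without KO P3 replicate 1) with 1 of 19 called (1 adjusted over the list alone), Myl1 (1.68 ± 0.51, adjusted p = 0.0204), which was lost without KO P3 replicate 1 (0.96, adjusted p = 0.247) or KO P0 replicate 3 (1.57, adjusted p = 0.0536) and with covariates (0.74, adjusted p = 0.0636). With these 2 groups alone Myl1 (adjusted p = 0.0948) and Defb1 (0.0800) lost their calls. In total 3174 genes differed, 1316 higher and 1858 lower, and 1902 without KO P3 replicate 1. After centring on the median there were 720 higher and 2954 lower.

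At P7 KO glands differed from P0 in 2730 genes, 1323 higher and 1407 lower (n = 5 and 4). Milk genes rose in 4 of 23 and fell in 5 (12 adjusted over the list alone), with Glycam1 at 4.35 ± 0.99 and Olah at 2.03 ± 0.50 against Ltf at -1.97 ± 0.44 and Aqp5 at -1.76 ± 0.14. Luminal progenitor markers rose in 7 of 15 and fell in 2 (10 adjusted over the list alone), with Rspo1 at 2.94 ± 0.46. Hormone-sensing luminal markers fell in 6 of 10 and rose in 1 (7 adjusted over the list alone), with Foxa1 at -1.37 ± 0.19 and Pgr at -1.39 ± 0.27 against Tnfsf11 at 1.48 ± 0.15, and camera adjusted p = 0.000728 became adjusted p = 0.258 with an estimated correlation. Erbb4 (1.27 ± 0.26) and Igf2 (1.55 ± 0.21) rose, and Ido1 (-5.64 ± 0.46), Clca1 (-4.24 ± 0.36), Pate6 (-3.99 ± 0.45), Cxcl15 (-3.52 ± 0.30) and Muc13 (-3.41 ± 0.32) fell. The count was 1727 without KO P0 replicate 1. Centring on the median moved the median of all genes by -0.11 and gave 776 higher and 2879 lower.

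At P10 KO glands carried the lymphocyte rise described above, with 15 of 16 B (1 lower) and 16 of 16 T markers higher than at P0 (16 and 16 adjusted over the list alone), Cd79a at 4.08 ± 0.66 and Cd3g at 3.18 ± 0.54 (n = 3 and 4). Without the arrays in doubt, which leaves KO P10 replicate 1 alone, Cd79a was 0.89 and Cd3g 1.21, and neither was called, nor with covariates (0.54 and 0.61). With these 2 groups alone Cd79a lost its call (adjusted p = 0.0520). Hormone-sensing luminal markers fell in 9 of 10 and rose in 1 (10 adjusted over the list alone), with Ptn at -2.90 ± 0.17, Foxa1 at -2.79 ± 0.22 and Pgr at -2.39 ± 0.31, and camera called them with the preset and the estimated correlation (adjusted p = 6.61e-09 and 0.0198). Milk genes rose in 9 of 23 and fell in 2 (12 adjusted over the list alone), with Glycam1 at 5.75 ± 1.12, Wap at 4.29 ± 0.70 and Olah at 3.70 ± 0.57. Pan-epithelial markers fell in 7 of 19 (7 adjusted over the list alone), with Krt7 at -2.12 ± 0.20 and Krt18 at -1.58 ± 0.19. Their list score was -0.52 and -0.55 in the lymphocyte-rich KO P10 replicates 2 and 3. In KO P10 replicate 1 it was -0.27, within the KO P0 range of -0.44 to 0.27. Camera called the B, T and milk lists (adjusted p = 7.23e-10, 1.13e-13 and 0.00646), lost with adjusted p = 0.310, 0.254 and 0.682 with an estimated correlation. Ido1 (-5.81 ± 0.53), Clca1 (-4.88 ± 0.41), Pate6 (-4.17 ± 0.51), Itih2 (-4.03 ± 0.36) and Cxcl15 (-3.80 ± 0.34) fell. Rspo1 rose (2.53 ± 0.52), a call lost without the arrays in doubt (2.78, adjusted p = 0.0516). In total 5172 genes differed, 2422 higher and 2750 lower, with 504 called without the arrays in doubt, 479 of them shared, and 3135 and 3267 without KO P10 replicate 2 and 3. Centring on the median moved the median of all genes by -0.21 and gave 1492 higher and 6441 lower, and quantile normalisation moved it by -0.13 and gave 2166 and 4362.

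At P15 milk genes rose in 21 of 23 and fell in 1 in KO glands (22 adjusted over the list alone; n = 4 and 4, with the array labelled KO day 15 replicate 3 counted as KO). Examples were Wap (6.03 ± 0.65, adjusted p = 1.13e-08), Glycam1 (6.02 ± 1.04, adjusted p = 2.16e-05), Olah (5.28 ± 0.53, adjusted p = 2.62e-09) and Cel (4.25 ± 0.56, adjusted p = 3.38e-07). Atp13a4 (4.90 ± 0.24), Pigr (4.60 ± 0.33), Gldc (4.54 ± 0.18), Elf5 (2.35 ± 0.33) and Erbb4 (1.76 ± 0.27) rose too. All 20 matrix genes fell (20 adjusted over the list alone), with Thbs2 at -2.50 ± 0.25, Fn1 at -1.85 ± 0.20 and Loxl1 at -1.66 ± 0.19. Macrophage markers fell in 14 of 17 (14 adjusted over the list alone), with Lyve1 at -3.55 ± 0.49 and Folr2 at -2.28 ± 0.35. Hormone-sensing luminal markers fell in 9 of 10 and rose in 1 (10 adjusted over the list alone), with Ptn at -3.68 ± 0.15, Foxa1 at -2.99 ± 0.20 and Pgr at -2.45 ± 0.29, and camera called them with the preset and the estimated correlation (adjusted p = 1.15e-07 and 0.0423). Camera called milk, matrix and macrophage genes (adjusted p = 5.97e-11, 3.91e-13 and 1.77e-06), lost with adjusted p = 0.111, 0.111 and 0.416 with an estimated correlation. Cell cycle genes were called in 0 of 33 (0 adjusted over the list alone), with a mean of -0.07 that was 0.29 without KO P0 replicate 4 and -0.25 without KO P0 replicate 1. Ido1 (-5.74 ± 0.49), Clca1 (-4.77 ± 0.38), Pate6 (-4.32 ± 0.47) and Itih2 (-3.96 ± 0.34) fell. In total 6962 genes differed, 3287 higher and 3675 lower. Centring on the median moved the median of all genes by -0.13 and gave 2017 higher and 5530 lower.

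**Figure D4:**
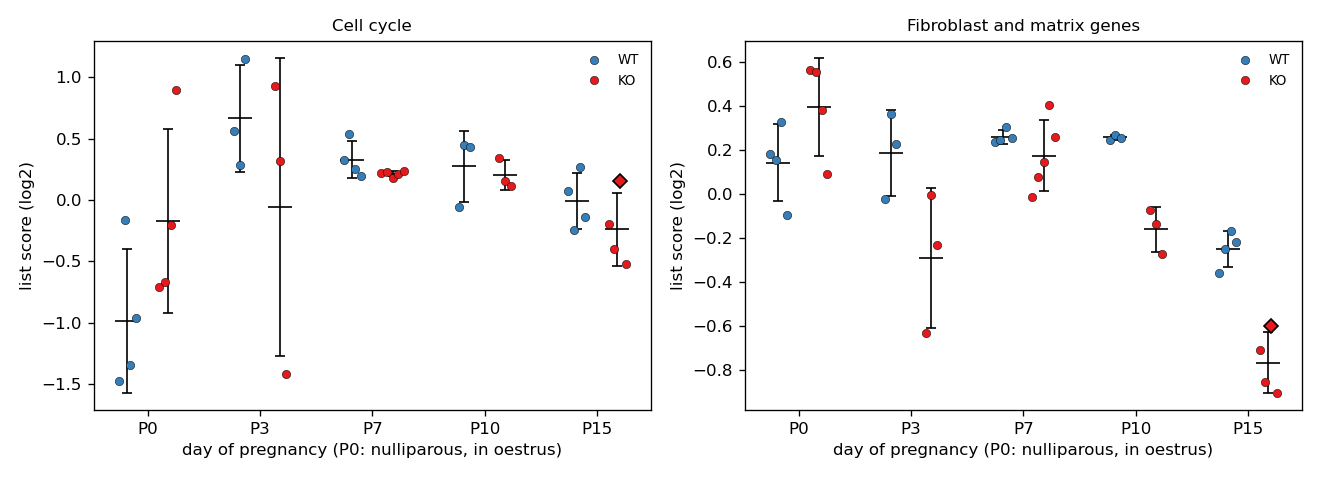
Scores of the cell cycle and matrix lists (log2, centred on the mean of all arrays, vertical axes) in each array by day of pregnancy for WT and KO glands; bars give the group mean and SD. The KO minus WT difference of the matrix score was 0.26 at P0 and -0.52 at P15, and the diamond is the array labelled KO day 15 replicate 3.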

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

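The tests of lymph node genes, of the lymphocyte markers in the remaining P10 array, of the position over genes called at P15, of the neighbours of Ptpn1 and of other splits were chosen after the results were seen. The median position over genes called at the other stages was set before its value was seen but after Slc2a10 and Ptgis had been seen in that array, and the position of the mean score is a second form of it that was not written down beforehand. In 174 sets (Ptpn1 or a list score in a group of 4 or 5 arrays), 12 had an array whose gap to its nearest neighbour was large for the range of the group, and chance picks about 1 in 20 groups.

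The array labelled KO day 15 replicate 3 carried Ptpn1 at 8.68, while the other KO P15 arrays lay between 5.36 and 5.70. Over 76 genes called in the mean over P0, P3, P7 and P10, a fit without P15 arrays, its median position between the WT P15 mean (0) and the mean of the other KO P15 arrays (1) was 0.154, and the position of its mean score over these genes was -0.0514, both of which a wild-type gland of another source under a knockout label could give. Without the lymphocyte-rich and muscle-rich arrays 6 genes were left, too few to weigh, and the position of the score was -0.145. Over 1780 genes called at P15 without it, the median position was 0.725, beside 0.83 to 0.91 for the other KO arrays and -0.01 to 0.33 for WT arrays. Of these genes 68.8% lay nearer the other KO arrays, against 32.0% in WT P15 replicate 2, the highest of the WT arrays. For these genes the values argue against a gland of the WT P15 group under a knockout label. The position did not reach the limit set for ruling it out, and Ptpn1 and the score over the 76 genes lay with WT. Whether a knockout gland could carry Ptpn1 at this level was not tested.

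Lymphocyte transcripts were higher at P10 in KO replicates 2 and 3. Lymph node tissue in these arrays is a candidate explanation, since a list of 4 measured lymph node stroma and venule genes had a median excess of 2.82 over the arrays that are not lymphocyte-rich. The excess was 4.204 for Cxcl13, 3.52 for Ccl19, 2.12 for Chst4 and 0.61 for Madcam1, and 3 of the 4 lay above every array that is not lymphocyte-rich. WT P7 replicate 1, which is also lymphocyte-rich, was not part of this comparison. A rise of lymphocytes with the loss of PTP1B stays open: the remaining KO P10 array lay above all WT P10 arrays in 14 of 32 B and T markers (43.8%, where chance gives 25%), which are not independent, 10 of 16 T markers but 4 of 16 B markers, and its B score of -0.251 lay below the lowest WT score of -0.248 while its T score of 0.103 lay above the highest of -0.135. Lymph nodes lie within mammary fat, and whether they were removed is not given in the sources used here.

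Genes near Ptpn1 on its chromosome differed between genotypes, with 5 of the 100 nearest called in the mean over stages (Slc2a10, Ptgis, Atp9a, Tshz2 and Zbp1) and 404 of the 16764 others. Among these neighbours Zbp1 was higher in KO (0.70) and the rest were lower, from -0.22 for Tshz2 to -0.52 for Ptgis. A donor-strain segment around the knockout allele may contribute, but Fisher's exact one-sided p was 0.0960 (odds ratio 2.13), while it was 0.00493 without the arrays in doubt, with 3 of 100 and 55 of 16764. An effect of the loss of PTP1B on its neighbours cannot be told apart from it, since the position of the array labelled KO day 15 replicate 3 over the called neighbours (0.0105) decides nothing: at P15 the other KO arrays lay above WT in Atp9a (9.21 against 9.10), opposite to its call, and hardly differed in Tshz2 (7.93 against 7.96). Per the labels the mice were backcrossed to FVB.

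The other arrays that stood apart were WT P0 replicate 2 in fatty acid synthesis (-0.70), KO P7 replicate 3 in oestrogen receptor targets (-0.0521), KO P0 replicate 1 in hormone-sensing luminal markers (0.58), WT P7 replicate 1 in B lymphocyte markers (1.10) and WT P0 replicate 3 in T lymphocyte markers (0.998). WT P0 replicate 4 stood apart in endothelial markers (0.10) and skeletal muscle markers (4.77), KO P7 replicate 3 in skeletal muscle markers (2.21), WT P7 replicate 3 and KO P7 replicate 1 in immediate early genes (0.29 and -0.13) and the array labelled KO day 15 replicate 3 in clock genes (-0.18).

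The genotype difference varied most clearly between stages by the F test in 10 genes. The adjusted p was 1.46e-06 for Ccnt1, 8.37e-06 for Alx4, 1.62e-05 for Pdgfrb, 1.79e-05 for Frem1, 9.18e-05 for Uqcr11 and Mrps26, 0.000106 for Dctn6, 0.000158 for Sh3pxd2b and Ugcg, and 0.000320 for Gcnt4.

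Other splits of the same arrays were tried for each count. For KO against WT at P0, 4 of 35 splits gave as many genes as the real 286 and the highest other gave 1432, so chance was not excluded, and a split with several times the real count points to a structure of the samples. That split set WT P0 replicate 2 and KO P0 replicates 2, 3 and 4, with pan-epithelial scores of 0.09 to 0.30, against the other P0 arrays, with scores of -0.96 to -0.44. At P3 the real 20 was beside a highest other of 6, and at P10 the real 2905 beside 1776, with 10 splits each, too few for a share below 0.05. At P7 1 of 100 splits gave as many genes (real 1, highest other 0), but that gene is Ptpn1, so this says nothing beyond the deleted gene. The share fell below 0.05 at P15 (1 of 35, real 1873, highest other 291), in the mean over stages (2 of 100, real 410, highest other 755, above the real count) and in the F test (1 of 100, real 3042, highest other 1022). For WT against P0, the share was not below 0.05 at P3 (2 of 35, real 3050, highest other 3860) or P10 (2 of 35, real 3603, highest other 4579). There the highest other split was near the real one, as it only moved WT P0 replicate 2 to the pregnancy arrays. Without that array the counts were 4033 at P3 and 5036 at P10, so a larger count there does not by itself speak for chance. At P7 (1 of 35, real 4940, highest other 2522) and P15 (1 of 35, real 8238, highest other 4791) the share fell below 0.05. For KO against P0 the share fell below 0.05 at P3 (1 of 35, real 3174, highest other 2489), P7 (1 of 100, real 2730, highest other 1698), P10 (1 of 35, real 5172, highest other 3018) and P15 (1 of 35, real 6962, highest other 1090). These shares are not adjusted over the contrasts, and with 35 splits none can go below 1 of 35. A split that mixes stages also widens the spread within its groups, which can lower its count, so chance is not excluded by these shares.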

How the results depend on the processing

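Leaving out the 7 arrays in doubt was added after the data were seen, and the other alternatives were set before. The adjustment over the 28 lists within each alternative was added later still. The interferon, plasma cell and matrix scores over all stages kept their direction and an unadjusted p below 0.05 under each alternative run. Adjusted over the lists, the interferon score passed in each, while the plasma cell and matrix scores were 0.101 with the replicate block and failed in 22 and 13 of 37 fits with 1 array left out, and matrix was 0.0505 without the arrays in doubt. Ptpn1 kept its direction. Nothing in the labels says that replicate numbers pair the arrays, and at no stage did every pair correlate over 0.1: 9 of 18 pairs did (-0.52 to 0.38), 8 best matched their own number, and at P15 replicates 2, 3 and 4 had 0.27, 0.32 and 0.38 against -0.14 for replicate 1. The setting of list members above the filter says nothing, since all members of the 4 lists it was run on passed the filter. The cause of each change was not tested. Intensity near the background limits dim genes, of which 3072 were not tested.

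In KO against WT, the P0 count was 175 after a further quantile normalisation, 439 with arrays centred on the median, 1103 with array weights, 104 without the arrays in doubt and 2 with the 2 groups alone. At P3 it was 12 centred, 8 with array weights, 9 with covariates, 8 with the replicate block, 2 without the arrays in doubt and 1 with the 2 groups alone. At P7 it was 3 with array weights, 2 with the replicate block and 2 with the 2 groups alone. At P10 it was 4495 over all probe sets, 4895 centred, 7340 with array weights, 0 with covariates, 1 without the arrays in doubt and 1 with the 2 groups alone. At P15 it was 4116 over all probe sets and 3330 with array weights. The mean over stages gave 3091 with array weights, 74 with covariates and 59 without the arrays in doubt. The F test gave 5403 over all probe sets, 5057 centred, 7877 with array weights, 844 with covariates and 492 without the arrays in doubt.

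Against P0, WT counts were 477 at P3 and 447 at P10 with the 2 groups alone, 7457 at P7 and 7233 at P10 with array weights, 2989 at P7 without the arrays in doubt and 13985 at P15 over all probe sets. KO counts were 1072 at P3 with the 2 groups alone, 4202 at P7 and 11299 at P15 over all probe sets. At P10 the KO count was 8429 over all probe sets, 7933 centred, 7992 with array weights, 678 with covariates, 504 without the arrays in doubt and 1827 with the 2 groups alone.

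With each array left out in turn, counts for KO against WT ran from 69 to 1811 at P0, 0 to 114 at P3, 1 to 1 at P7, 841 to 4872 at P10, 1294 to 1873 at P15, 156 to 1831 in the mean and 1540 to 4939 in the F test. Against P0 they ran from 1072 to 4033, 3492 to 6134, 1610 to 5036 and 7403 to 8769 in WT and from 1902 to 3480, 1727 to 2838, 3135 to 6218 and 6266 to 6861 in KO. Ptpn1 ran from -3.11 to -2.80 at P0, -2.94 to -2.83 at P3, -2.98 to -2.69 at P7, -2.83 to -2.63 at P10, -3.03 to -1.93 at P15 and -2.87 to -2.65 in the mean. It lost its call at P3 without KO P3 replicate 3 (-2.93) and at P10 with covariates (-2.68), in fits that held the array labelled KO day 15 replicate 3.

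The milk score over all stages ran from 0.21 to 0.33 with each array left out, passed the unadjusted threshold in 31 of 37 fits, and was 0.27 (p = 0.0580, permutation) with the replicate block. By stage it ran from 0.04 to 0.46, 0.06 to 0.71, 0.10 to 0.38, 0.13 to 0.51 and 0.05 to 0.17, and at P15 the median over the list was 0.38 (unadjusted exact permutation p = 0.0286). The interferon score ran from 0.46 to 0.61, plasma cell from 0.20 to 0.25 and matrix from -0.28 to -0.21. At P10 Ms4a1 turned to -0.59 with covariates and -0.19 without the arrays in doubt, and Ccr7 to -0.0269 with covariates. Slpi at P7 passed the threshold with array weights (adjusted p = 0.0219), with the replicate block (-1.53, adjusted p = 0.00493) and with the 2 groups alone (adjusted p = 0.00439).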

Other observations

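The gene families of the P15 comparison below were chosen after the data were seen, and their p values are unadjusted. Nuclear genes of the respiratory chain and ATP synthase were higher in KO glands at P15, with 20 of 74 called higher and 0 lower, and a mean score difference of 0.32 (two-sided exact permutation p = 0.0286, n = 4 against 4). The array labelled KO day 15 replicate 3 scored 0.12, the other KO arrays -0.15 to -0.02 and WT arrays -0.42 to -0.32. Mitochondrial ribosomal protein genes were higher in 24 of 77 with 0 lower (difference 0.25, exact permutation p = 0.0286), and that array scored 0.12. Cytosolic ribosomal protein genes were higher in 10 of 53 with 0 lower (difference 0.16, exact permutation p = 0.0286). Of all 16865 tested genes 1143 were called higher at P15 and 730 lower. Without the array labelled KO day 15 replicate 3 the differences of the 3 families were 0.27, 0.21 and 0.17. With an estimated correlation camera gave unadjusted p = 0.210, 0.0960 and 0.353 for the 3 families. Brown adipocyte markers scored 0.82 higher in KO glands at P15 as well (exact permutation p = 0.0286, adjusted over the 28 lists 0.2). That list and the respiratory chain family share Cox8b, so they are not separate results. A difference in cell types was not separated from one within cells.

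The KO minus WT differences at P0 and at P3, which share no array, had a Pearson r of -0.489 and a Spearman rho of -0.378 across 16864 genes, which are not independent replicates. Of 285 genes called at P0, Ptpn1 left out, 217 had the opposite sign at P3 (76.1%), as had 10648 of all 16864 genes (63.1%). Without the lymphocyte-rich and muscle-rich arrays r was -0.304, rho was -0.271 and 73 of 112 had the opposite sign (65.2%), as had 59.9% of all genes. Of 28 list scores 14 changed sign, as many as kept it, a share that no relation between the stages would also give. The widest gaps were for skeletal muscle (-1.57 and 1.90), cell cycle (0.81 and -0.72), brown adipocyte (-0.61 and 0.74), macrophage (0.63 and -0.35) and matrix genes (0.26 and -0.48). With 1 array left out, the P3 differences nearest 0 were 0.17 for muscle (KO P3 replicate 1), -0.04 for cell cycle (KO P3 replicate 3), 0.20 for brown adipocyte (WT P3 replicate 2), 0.03 for macrophage and -0.31 for matrix genes (both KO P3 replicate 1). At P0 they were -0.39 for muscle (WT P0 replicate 4), 0.46 for cell cycle (KO P0 replicate 4), -0.31 for brown adipocyte (WT P0 replicate 1) and 0.38 for macrophage markers (WT P0 replicate 2). Slpi was lower in KO glands at both stages, with -1.99 ± 0.36 at P0 and -2.11 ± 0.42 at P3.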
